A study of Taeniopygia guttata with 169 samples.

How the data were processed

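RNA of whole bone marrow was prepared with an RNAzol reagent, messenger RNA was drawn out on oligo(dT) beads, and libraries were made with NEBNext Ultra II reagents, per the labels' protocols. The submitters' processing notes name featureCounts, Subread, DESeq2 1.30.1 and R 4.0.2, and the genome build, annotation and strand setting are not given in the sources used here, so reads of overlapping or antisense genes may be shared. The deposited values are a normalised signal per gene: read counts divided by 1 size factor per library, by the authors. This was checked on the values: each library's lowest value above 0 was taken as 1 read, 100% of values were then whole within a relative tolerance of 1e-06, and the factors (0.574 to 1.75) equal DESeq2's median of ratios, recomputed on the recovered reads, to 4.7e-15. The table has 17292 genes with Ensembl identifiers. Each has at least 58 reads over all libraries.

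Treatment, age, sex, cohort, plate, RNA extraction batch and RIN came from the labels. Of 169 labelled libraries, 161 have a column in the table and were analysed. The other 8 were not analysed here, 7 of unknown sex and 1 MeHg male of day 6. The libraries analysed lie on 11 plates and in 20 extraction batches. RIN is labelled for 127 of them, and for none on plates A and C or in some extraction batches. Tests with RIN thus leave out these plates and batches. The title codes, 34 in all and 45 when counted within cohort, belong to 1 treatment each. The largest holds 15 birds. Titles also carry a colour, whose meaning is not stated and which was not used in the fits. Some libraries share both colour and code, and those that share cohort too differ in age at euthanasia. Birds with the same code may be related or housed together, and the labels do not say.

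The design written before the data were examined assumed raw counts and edgeR. Since the deposited values are normalised, the main test became limma 3.58.1 (R 4.3.3) with a trend and robust variances on log2(value + 1), and edgeR 4.0.16 on recovered reads became an added alternative. That test called 1066 genes for the mean MeHg difference, 889 of them among limma's 1050. Genes with a value of at least 10 in at least 15 libraries were tested, 14042 in all. The pseudocount and this filter were chosen after the file was opened. A single fit held 8 treatment-by-age groups with sex, cohort and plate as covariates. Plate D has a sole analysed library, a control of day 6, which therefore added nothing to the contrasts of fits with plate. Contrasts were MeHg against control at each age and over the mean of 4 ages, steps between successive ages in each treatment, sex and cohort. Interactions of MeHg with age (3 degrees of freedom), sex and cohort were tested too. Sex by age was added later. Calls have a Benjamini-Hochberg adjusted p under 0.05.

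The reference table of the bTaeGut7.mat assembly paired 0 of the identifiers with a symbol. For that reason the 36 gene lists fixed beforehand (telomere, DNA repair, stress, blood and other cell types) and their set tests could not be run, genes have no names or positions here, and genes that share reads with near-identical copies could not be recognised. The rule for named genes asked for symbols. Its order was kept without them: up to 2 genes each way with the largest changes past the threshold and an average log2 CPM of at least 1, or 3 for age steps, and for cohort and its interaction with MeHg up to 2 each way among the 5 smallest p. For MeHg the genes of the mean contrast are shown at single ages.

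Within groups no pair of libraries came near sampling noise: the lowest chi-square per gene of any pair was 13.3. Sex labels were tested on genes picked with those labels. On 11 genes at least 4-fold higher in females and on the 50 genes higher in males with the smallest p, 0 libraries lay on the side of the other sex. An earlier form rested on 1 gene, with a median of at least 50 in females and at most 5 in males, and put 7 males past the midpoint of the medians of the sexes, although the lowest female (4.34 on the log2 scale) lay above the highest male (4.13). Totals, RIN and the share of the 3 most abundant genes (16.8% of normalised counts) were compared between treatments by permutation with 100000 resamples.

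The fits were tested on simulated counts drawn from the real genes' means, spreads and size factors, with 200 of 14042 genes changed. For the mean MeHg difference, 64% of genes changed 1.25-fold, 86% of those changed 1.5-fold, 100% at 2-fold and 96% at 4-fold were recovered, and 8 of 181 calls were unchanged genes. For MeHg at day 90, 28%, 50%, 78% and 92% were recovered, and for MeHg by age 12%, 32%, 60% and 86%. The simulated birds were independent, and each gene had 1 spread, pooled over the groups. The recovery thus does not carry over to groups with a wider spread or outlying libraries.

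Alternatives covered the pseudocount, the filter, TMM scaling, edgeR, DESeq2 1.42.0, voom with quality weights, covariates (none, extraction batch, RIN, log2 total, 5 surrogate variables from sva 3.50.0), the title code as a random effect, subsets by sex, cohort and age, and plates, codes and day 90 libraries left out in turn. Both edgeR fits use edgeR's own filter. Splits of the libraries were drawn with fixed seeds, 99 besides the real one. Splits that kept title codes whole did not keep the group sizes.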

Results

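Gene expression was profiled by RNA sequencing in bone marrow of zebra finches, a songbird whose blood cells form in the marrow. Birds received a control diet or food with methylmercury (MeHg, an organic form of mercury) at 1.2 ppm and were sampled at day 6, 18, 35 or 90. The series asks how this dose, described as sublethal, affects the blood-forming system. The table analysed holds 78 control and 83 MeHg libraries, each counted here as 1 bird: 17 control and 15 MeHg libraries at day 6, 21 and 25 at day 18, 19 and 21 at day 35, and 21 and 22 at day 90. There were 74 females and 87 males. Every group held birds of both sexes and of both labelled cohorts. Totals ranged from 4572638 to 14968673 assigned reads per library, with a median of 7637898. The labels do not state in words that each library came from a separate bird, so p-values measure the spread between these libraries. Values are normalised read counts, and fold changes are on the log2(value + 1) scale, which understates changes of weakly expressed genes.

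The first principal component followed age. It held 22.8% of the variance of 14042 genes, and age alone explained 91.7% of it, extraction batch alone 20.6%, plate 20.0%, title code 9.2%, treatment 0.60%, sex 0.55% and cohort 0.43%. Between treatments of 1 age, totals, RNA integrity (RIN) and the share of reads in the 3 most abundant genes did not differ beyond chance in any of 12 permutation tests (two-sided, 100000 resamples; lowest adjusted p = 0.363). RIN was lower in the youngest birds, with a mean of 7.64 ± 0.61 (SD, n = 27) at day 6 against 8.66 ± 0.40 (SD, n = 32) at day 18.

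**Figure D1:**
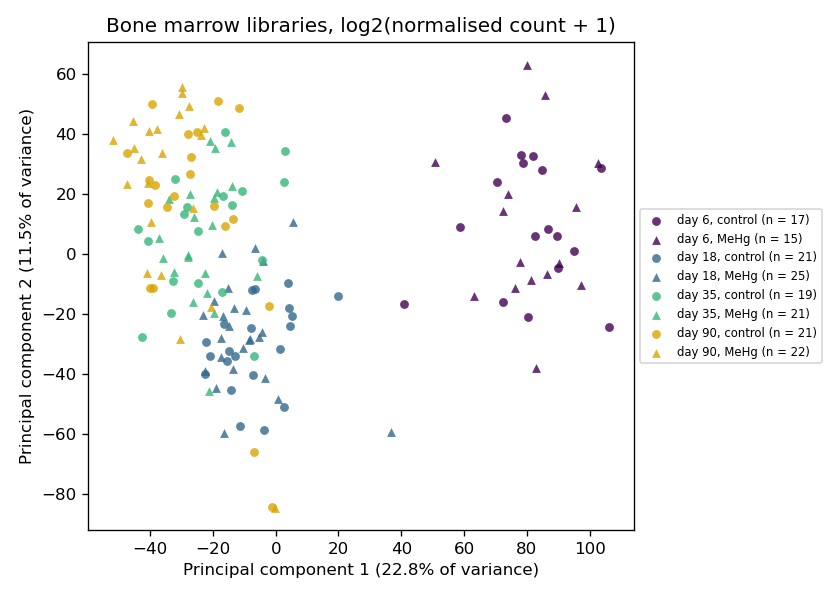
Each point is a library on the first 2 principal components of log2(normalised count + 1), coloured by age, with circles for control and triangles for MeHg birds. Day 6 libraries lie apart on the first component, and the treatments overlap at each age.

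The step from day 6 to day 18 in control birds addressed early development of the marrow. In this step 8658 of 14042 genes changed, 4460 upward and 4198 downward, and 2392 of them changed at least 2-fold. The median absolute change was 0.66 on the log2 scale. ENSTGUG00000021471 rose from 8.76 ± 5.41 (SD, n = 17) to 701 ± 497 (SD, n = 21) normalised counts, a log2 fold change of 6.11 ± 0.39 (SE; limma, adjusted p = 2.36e-30). ENSTGUG00000026720 rose from 13.3 ± 9.59 to 980 ± 448 normalised counts (log2 fold change 5.93 ± 0.22 SE, adjusted p = 3.11e-54), and it stayed high at 709 ± 213 (SD, n = 19) at day 35 and 776 ± 348 (SD, n = 21) at day 90. ENSTGUG00000011952 fell from 1068 ± 817 to 8.60 ± 12.4 normalised counts (log2 fold change -6.76 ± 0.34 SE, adjusted p = 6.44e-40). ENSTGUG00000005669 fell from 357 ± 214 to 3.31 ± 2.54 normalised counts (log2 fold change -6.05 ± 0.35 SE, adjusted p = 5.65e-34), and both genes remained below 5 normalised counts on average at day 35 and day 90. Symbols are not given for these identifiers, since the files and the reference table used here do not pair them with names.

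From day 18 to day 35, 4472 genes changed in controls, 2355 upward and 2117 downward, with a median absolute change of 0.40. ENSTGUG00000029343 rose from 48.3 ± 43.04 (SD, n = 21) to 1738 ± 1596 (SD, n = 19) normalised counts (log2 fold change 4.80 ± 0.40 SE; limma, adjusted p = 4.09e-19). ENSTGUG00000028531 rose from 83.7 ± 64.1 to 1882 ± 1560 normalised counts (log2 fold change 4.02 ± 0.36 SE, adjusted p = 8.15e-18). At day 90 their means were 1506 and 1835 normalised counts. ENSTGUG00000027415 fell in this step from 268 ± 452 to 3.15 ± 2.07 normalised counts (log2 fold change -4.79 ± 0.41 SE, adjusted p = 4.09e-19), after a mean of 1551 at day 6. ENSTGUG00000012726 fell from 986 ± 436 to 351 ± 263 normalised counts (log2 fold change -1.81 ± 0.41 SE, adjusted p = 0.000284).

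Of the 3010 genes called in both of these steps, 2200 turned direction: 1029 rose and then fell, and 1171 fell and then rose. A further 481 rose in both steps and 329 fell in both. Independent lists of the same lengths would give 1376 turns and 1381 genes moving in 1 direction. The 2 steps share the day 18 controls, which alone makes turns more frequent. With those controls parted at random so that the steps shared no day 18 library, 71.6% of the genes called in both steps turned (mean of 20 draws, range 65.2% to 77.9%), against 73.1% with all of them. Across all genes the covariance of the 2 steps was -0.0224 with shared controls and -0.0115 with the controls parted, and simulations with shared controls and no effect gave -0.0162.

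Few genes changed from day 35 to day 90 in controls, with 64 called upward and 55 downward. ENSTGUG00000001295 rose from 36.6 ± 21.4 (SD, n = 19) to 134.2 ± 75.6 (SD, n = 21) normalised counts (log2 fold change 1.73 ± 0.30 SE; limma, adjusted p = 8.63e-05). ENSTGUG00000006579 fell from 522 ± 369 to 72.1 ± 47.1 normalised counts (log2 fold change -2.98 ± 0.39 SE, adjusted p = 1.88e-08), and ENSTGUG00000022429 fell from 127.5 ± 99.8 to 37.1 ± 26.2 (log2 fold change -1.95 ± 0.33 SE, adjusted p = 6.88e-05). ENSTGUG00000013081 had the largest rise among genes with an average log2 CPM of at least 3 (log2 fold change 1.75 ± 0.46 SE, adjusted p = 0.0328), but its day 90 mean of 437 ± 877 normalised counts stood beside a median of 23.7. It no longer passed without covariates (log2 fold change 1.65, adjusted p = 0.0583), on the libraries with a RIN (1.92, adjusted p = 0.0591), with RIN added on these (1.82, adjusted p = 0.0914) or with surrogate variables (1.29, adjusted p = 0.0606). The same held without the 3 libraries farthest from their groups on the first 2 principal components, all of day 90 females (log2 fold change 1.18, adjusted p = 0.143). Over all ages and both treatments the highest value of ENSTGUG00000013081 was 76.9 normalised counts in males and 2574 in females. The count of genes in this step was 62 on the libraries with a RIN, 54 with RIN added on these, 248 by DESeq2 and 589 by voom.

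MeHg birds went through similar steps. They had 8088 genes called from day 6 to day 18, 4353 from day 18 to day 35 and 466 from day 35 to day 90. Of these, 7251, 2953 and 63 were also called in controls in the same direction, and 0 in the opposite direction. Independent lists would share 2495, 694 and 2.06 genes in direction. The correlation of fold changes across genes, which are not independent replicates, was 0.94 for the first step, 0.74 for the second and 0.50 for the last. The last step in MeHg birds leaned upward, with 371 genes up and 95 down. Voom called 2218 genes there with a weaker lean, 1328 up and 890 down, and the fit without the 3 farthest libraries 887. A difference between treatments in the steps is tested by the MeHg by age interaction.

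Within single ages, limma called few genes between MeHg and control birds. It called 5 genes at day 6 (3 up, 2 down), 18 at day 18 (12 up, 6 down), 11 at day 35 (7 up, 4 down) and 28 at day 90 (17 up, 11 down). Only 3 genes were called at 2 or more ages. At an unadjusted p under 0.05 the counts were 797, 1602, 1247 and 2133. The single-age counts moved with individual libraries and with the tool: the edgeR quasi-likelihood test called 27, 35, 29 and 75 genes and voom 40, 272, 257 and 494. With day 90 libraries left out in turn the day 90 count ranged from 7, without control replicate 15, to 359, without MeHg replicate 7.

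Over the mean of the 4 ages, 1050 of 14042 genes were called between MeHg and control birds, 531 higher and 519 lower with MeHg. This fit and its p-values took the birds as independent, although each title code belongs to 1 treatment. The differences were small, with a median absolute change of 0.30 on the log2 scale, and 35 genes differed at least 2-fold. Among called genes with an average log2 CPM of at least 1, ENSTGUG00000005933 had the largest rise (log2 fold change 2.18 ± 0.36 SE; limma, adjusted p = 6.8e-06). At day 18 it had 46.9 ± 48.01 (SD, n = 25) normalised counts in MeHg birds and 6.68 ± 24.5 (SD, n = 21) in controls, and at day 90 54.6 ± 67.1 (SD, n = 22) and 8.01 ± 19.6 (SD, n = 21). By single age it passed at day 18 alone (adjusted p = 0.0172), against 1 at day 6, 0.243 at day 35 and 0.09 at day 90. At day 6 (log2 fold change 1.296 ± 0.82 SE) the control mean was the higher, 61.5 ± 165.7 (SD, n = 17) against 43.8 ± 52.97 (SD, n = 15), with medians of 3.22 and 9.42. ENSTGUG00000004149 rose by 1.73 ± 0.29 (SE, adjusted p = 9.03e-06), with 100 ± 116.5 (SD, n = 15) normalised counts in MeHg birds and 6.59 ± 5.77 (SD, n = 17) in controls at day 6, where the medians were 14.1 and 5.42, and 40.1 ± 43.1 (SD, n = 22) against 13.4 ± 23.1 (SD, n = 21) at day 90, where the medians were 12.8 and 7.59. It passed at no single age (adjusted p = 0.214, 0.269, 0.18 and 0.245), and it was among the genes called for MeHg by cohort, with a log2 difference of 2.86 in cohort 1 and 0.79 in cohort 2. ENSTGUG00000007021 fell (log2 fold change -1.59 ± 0.32 SE, adjusted p = 0.000278), with 55.2 ± 63.2 normalised counts in day 18 controls and 20.0 ± 40.9 in day 18 MeHg birds, where it did not pass by itself (adjusted p = 0.0799). ENSTGUG00000005610 fell too (log2 fold change -1.52 ± 0.24 SE, adjusted p = 4.24e-06), with 22.4 ± 20.0 normalised counts in controls and 4.96 ± 8.78 in MeHg birds at day 18 (adjusted p = 0.0139 at that age). In each of these 4 genes the ranges of both treatments overlapped, and not only through single birds. In MeHg birds ENSTGUG00000005933 had medians of 9.42 at day 6 and 8.33 at day 35, against means of 43.8 and 47.5. Its medians at day 18 and day 90 were 39.2 and 40.6. The MeHg medians of ENSTGUG00000004149 were 16.8 at day 18 and 59.2 at day 35, against means of 75.5 and 60.8.

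**Figure D2:**
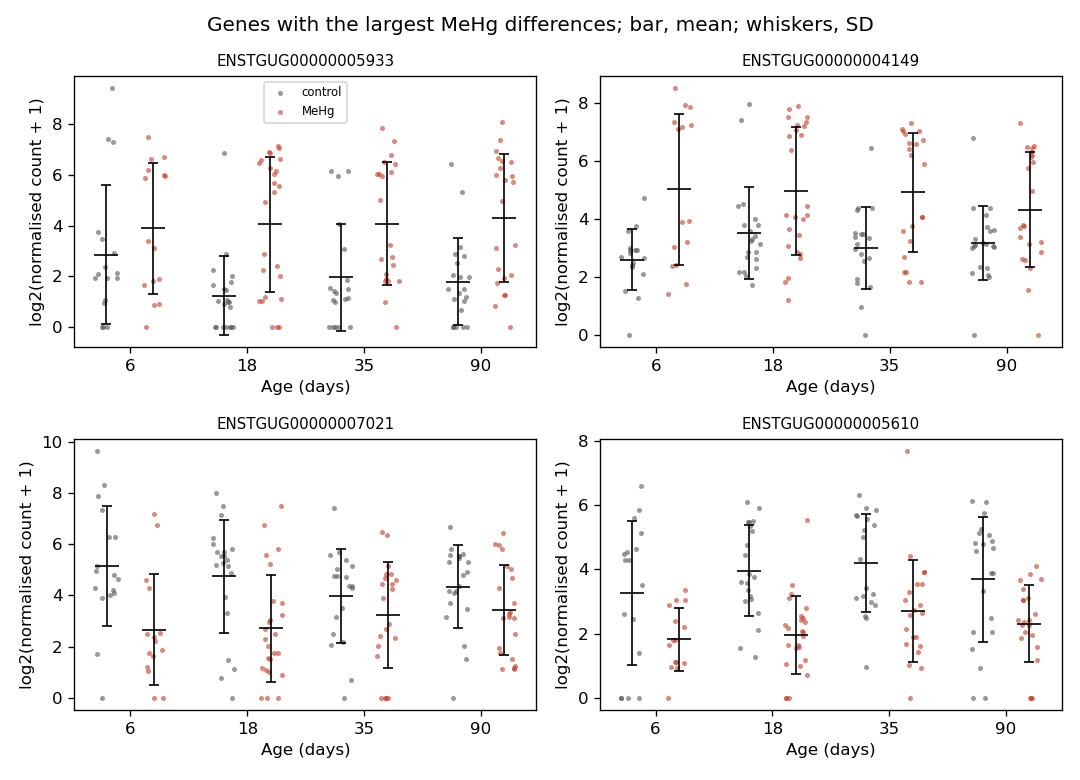
Each point is a library, by age in days and treatment, on a log2(normalised count + 1) axis, with bars for the mean and whiskers for the SD. ENSTGUG00000005933 and ENSTGUG00000004149 are higher and ENSTGUG00000007021 and ENSTGUG00000005610 lower on average in MeHg birds, and the ranges of both treatments overlap.

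The birds' titles carry 34 codes, 18 in controls and 16 in MeHg birds, whose meaning is not stated, and the design text speaks of birds with differing exposure histories. With the code within cohort as a random effect 430 genes were called over the mean, all of them among the 1050. Males alone gave 247 genes, females alone 69, cohort 1 alone 593 and cohort 2 alone 398. Each of the 4 named genes kept its direction but failed to pass in at least 1 of these subsets. ENSTGUG00000005933 did not pass in females (log2 fold change 2.03, adjusted p = 0.0624) or in cohort 1 (1.54, adjusted p = 0.112), and ENSTGUG00000004149 did not in cohort 2 (0.74, adjusted p = 0.391). ENSTGUG00000007021 did not pass in males (log2 fold change -1.32, adjusted p = 0.148) or in cohort 2 (-0.83, adjusted p = 0.418), and ENSTGUG00000005610 did not in females (-1.03, adjusted p = 0.237).

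No gene passed the test of whether the MeHg difference varied between ages (limma, 3 degrees of freedom; 754 genes at an unadjusted p under 0.05, lowest adjusted p = 0.52). The edgeR and DESeq2 tests called 5 genes each and voom 1. No gene passed the MeHg by sex test either (limma; 473 genes at an unadjusted p under 0.05), and edgeR and DESeq2 also called 0.

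The fit of MeHg by cohort and its p-values, like those of the mean, took the birds as independent, although each title code belongs to 1 treatment. In this fit the MeHg difference varied between the 2 cohorts. The interaction test called 365 genes. In 326 of them the estimates of the 2 cohorts had opposite signs, which choosing genes by a large difference favours by itself, and the MeHg difference passed in cohort 1 for 189 of the 365 and in cohort 2 for fewer than that. ENSTGUG00000029089 was lower with MeHg in cohort 1 (log2 -0.74 ± 0.11 SE) and higher in cohort 2 (log2 0.36 ± 0.10 SE; limma, adjusted p of the difference = 1.18e-07). ENSTGUG00000002789 went the other way, with log2 differences of 0.35 ± 0.06 (SE) in cohort 1 and -0.21 ± 0.05 (SE) in cohort 2 (adjusted p = 1.18e-07), as did ENSTGUG00000023659 with 0.65 ± 0.11 (SE) and -0.35 ± 0.10 (SE; adjusted p = 6.13e-07). Fitted in each cohort alone, 593 and 398 genes were called, of which 39 were shared in direction and 14 shared in opposite directions, where independent lists would give 8.45 and 8.36. Across genes the MeHg differences of the 2 cohorts had a correlation of 0.13. With the title code within cohort as a random effect 0.79% of genes were called in place of 2.6%, and with extraction batch in place of plate 209 genes were.

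**Figure D3:**
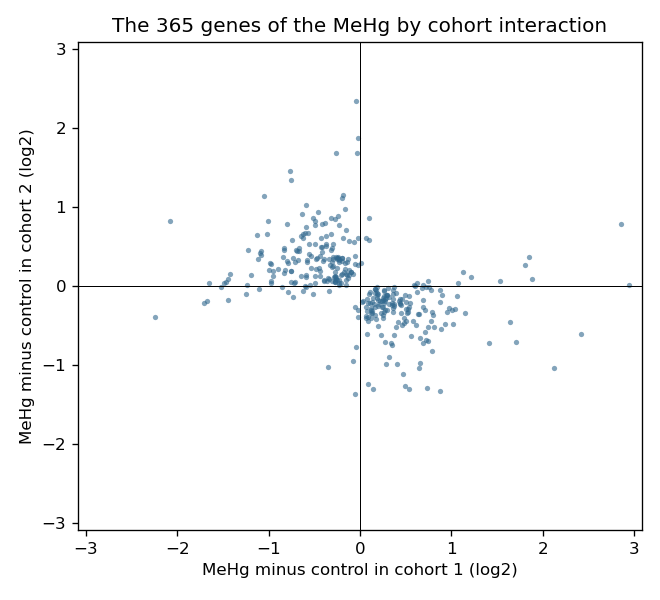
Each point is 1 of the 365 genes of the MeHg by cohort interaction, with the MeHg minus control log2 difference in cohort 1 on the x axis and in cohort 2 on the y axis. Estimates of 326 genes lie in the quadrants of opposite sign, some of them near 0 in 1 cohort.

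Between cohorts themselves, 2246 genes differed, 1186 higher and 1060 lower in cohort 2, with a median absolute change of 0.24. ENSTGUG00000029027 was higher in cohort 2 (log2 fold change 0.49 ± 0.06 SE; limma, adjusted p = 3.49e-10), as was ENSTGUG00000027979 (1.12 ± 0.14 SE, adjusted p = 1.93e-09). ENSTGUG00000022946 was lower (log2 fold change -0.68 ± 0.08 SE, adjusted p = 9.17e-10), as was ENSTGUG00000027191 (-0.33 ± 0.04 SE, adjusted p = 1.93e-09). What distinguishes the cohorts is not stated in the labels, and the count was 1076 with the title code within cohort as a random effect.

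Male and female birds differed in 1134 genes over all ages. The 629 genes higher in males had a median log2 difference of 0.81, with 25% under 0.58 and 25% over 0.95, and 83.5% of them exceeded 0.5. The 505 genes higher in females had a median of -0.14, and 8.5% of them lay beyond -0.5. In birds males carry a pair of Z chromosomes and females a Z and a W. ENSTGUG00000024281 had 53.8 ± 18.2 (SD, n = 74) normalised counts in females and 1.42 ± 3.07 (SD, n = 87) in males (log2 male minus female -4.95 ± 0.14 SE; limma, adjusted p = 7.97e-70). ENSTGUG00000026388 had 120 ± 78.8 in females and 6.04 ± 4.53 in males (log2 -4.20 ± 0.16 SE, adjusted p = 1.3e-54). ENSTGUG00000022124 was higher in males, with 23.8 ± 20.9 against 6.24 ± 11.5 normalised counts (log2 2.12 ± 0.26 SE, adjusted p = 4.09e-12), as was ENSTGUG00000021286 with 20.8 ± 17.5 against 7.47 ± 10.6 (log2 1.75 ± 0.21 SE, adjusted p = 3.45e-12). By age the sexes differed in 494 genes at day 6, 650 at day 18, 853 at day 35 and 3256 at day 90. A test of sex by age called 1338 genes, and 591 without MeHg day 90 replicate 7. Without the 3 farthest libraries, all of day 90 females, only 8.9% of the 1338 stayed called, and the sexes differed in 773 genes at day 90.

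**Figure D4:**
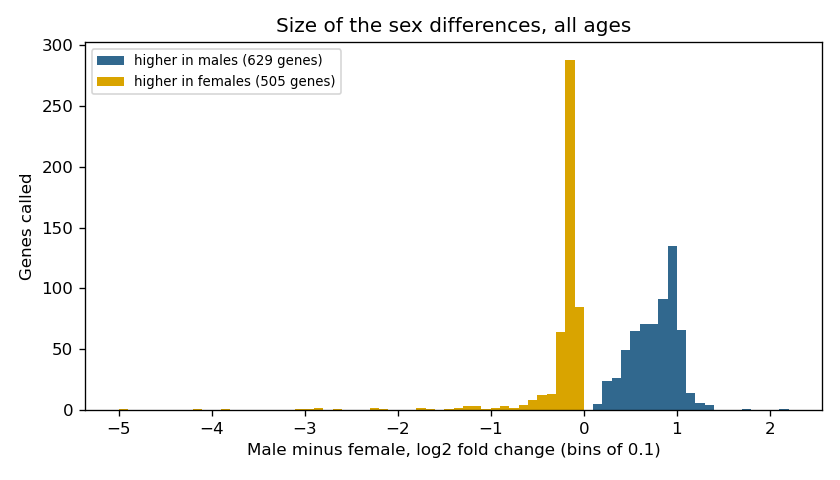
Histogram of the 1134 genes that differed between the sexes, with the male minus female log2 fold change on the x axis in bins of 0.1 and the number of genes on the y axis. The 629 genes higher in males gather below 1, around a median of 0.81, and most of the 505 genes higher in females lie near 0.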

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

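The tests of whole title codes and of agreement between ages for the mean MeHg difference, the tests of the 3 day 90 libraries, the splits of libraries for the MeHg contrasts and the choice of sex by age as a result were made after related results were seen.

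The MeHg difference varied between cohorts in 365 genes. When cohort labels were redrawn within groups, 1 of 100 splits, the real one, called as many, and the highest other called 1. These splits moved birds singly and broke up title codes, of which 11 of 34 occur in both cohorts. They therefore do not test resemblance within codes. When treatment was redrawn with title codes kept whole, 3 of 100 called as many, with a highest of 797. These redrawn groups could hold fewer birds than the real ones, which can lower their counts. With the title code within cohort as a random effect 0.79% of genes were called in place of 2.6%. Resemblance of birds that share a code thus stays open as a contributor. RNA quality could be tested only on libraries with a RIN, which called fewer genes than 365 and include none of plates A and C. Of the genes called there, 86.6% stayed called with RIN in the fit. This argues against RNA quality for those genes and leaves it open for the rest of the 365. Extraction batch stays open: 53.4% of the 365 genes stayed called with batch in place of plate. A difference of origin or exposure history between the cohorts' birds is untested and may also contribute.

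The male to female difference varied with age in 1338 genes, and 1 of 100 splits of sex within groups called as many (highest other 99). At day 6, 18, 35 and 90 the sexes differed in 494, 650, 853 and 3256 genes. The 3 libraries farthest from their groups on the first 2 principal components are all of day 90 females of cohort 2, MeHg replicate 7 and control replicates 15 and 16, on 3 different plates. Without them day 90 had 773 genes, and 8.9% of the 1338 interaction genes stayed called, whereas the interaction count without 3 other day 90 females at random was 1001 to 2377 in 20 draws. These 3 birds may thus account for most of the pattern. They had the 3 lowest numbers of genes with a read among all libraries (15014, 14871 and 15211, in the order named). What sets them apart, such as reproductive state or the cells sampled, could not be tested. RNA quality stays open, with 59.1% of the 1208 genes called on libraries with a RIN still called with RIN in the fit.

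The mean MeHg difference of 1050 genes was reached by 1 of 100 splits of treatment within ages, the real one (highest other 1). With title codes kept whole it was also 1 of 100, and the others had a median of 2 genes, a 90th percentile of 60.6 and a highest count of 927. These splits could leave fewer birds in a group than the real one, which can lower their counts. They therefore cannot exclude resemblance within codes. The called genes also had a median within-code correlation of residuals of 0.120, above the 0.0882 that marks the 95th percentile of 10000 expression-matched lists. Resemblance within codes may thus add to the count. The lists were drawn gene by gene and called genes may vary together, so the percentile cannot say how likely this is. RNA quality is argued against for the 550 genes called on libraries with a RIN, of which 98.2% stayed called with RIN. Depth is argued against too, since 97.3% of the 1050 stayed called with the log2 total in the fit. An effect that repeats at each age predicts agreement between ages, and the mean correlation of fold changes between ages was 0.347, reached by 1 of 100 splits with whole codes (highest other 0.290). Smaller groups in those splits can lower this correlation too. Agreement between cohorts was low, with a correlation of 0.13 across genes. Fitted alone, they called 593 and 398 genes, 39 shared in direction and 14 in opposite directions, where independent lists would give 8.45 and 8.36. Each of these fits held the birds of 1 cohort only, which can lower the overlap. The agreement between ages leaves open a difference in descent between the treatments' birds, since every code belongs to 1 treatment.

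For MeHg at single ages, as many genes were called by 2 of 100 splits at day 18 (highest other 60), 3 at day 35 (highest other 1024) and 3 at day 90 (highest other 2206). At day 6 it was 6 of 100 (highest other 237), so chance was not excluded there. With title codes kept whole it was 17 of 100 at day 6, 2 at day 18, 1 at day 35 and 6 at day 90, so the day 90 count was not beyond resemblance within codes. Group sizes were not kept in these splits, so the values at day 18 and day 35 do not exclude such resemblance. For the age steps 1 of 100 splits, the real one, called as many in each case. The highest other was 4904, 2 and 3 genes in controls and 3079, 17 and 217 in MeHg birds. The same held for sex over all ages (highest other 1) and cohort (2246 genes). The cohort splits did not keep title codes whole, and with the code within cohort as a random effect the cohort count was 1076. For MeHg by age and MeHg by sex the count of splits says nothing about chance, since with 0 genes called all 100 splits call as many by construction. In the first control step 87.6% of the 7653 genes called on libraries with a RIN stayed called with RIN, and 97.7% of 8658 without plate H, which holds 5 libraries of day 6. The fit has a term for each plate, and plate H holds day 6 libraries alone. Leaving it out could thus hardly change this step and does not test an effect of plates.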

How the results depend on the processing

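The tests with other pseudocounts, TMM scaling, edgeR with TMM, the log2 total, the code over both cohorts, libraries with a RIN as reference, without plate H or the 3 farthest libraries, the codes and day 90 libraries left out, and everything on sex by age were chosen after seeing the data. No paired analysis was possible because replicate numbers only name libraries in accession order, ages are labelled as ages at euthanasia, so that a bird has only 1 of them, and each code belongs to 1 treatment. Title codes, plates and batches do run across groups and were fitted as a random effect or covariates. Camera, fry and the gene lists were not run for lack of symbols, and leaving out libraries of unknown sex or under 0.5 of the median total removed none. Surrogate variables and the code as a random effect were fitted on log2 values, where the plan named counts. At the depth, spread and group sizes of these data, 50% of simulated 1.5-fold and 78% of 2-fold changes were recovered for MeHg at day 90. Of 529 fold changes of named genes under alternatives, 0 reversed and 11 no longer passed. These genes were chosen for large changes or small p in the same libraries, which by itself makes reversals rare. Fits with plates, codes or day 90 libraries left out in turn were not among the 529.

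Values here are the percent of the genes tested in each fit that were called. The reported fit called 0.0356%, 0.128%, 0.0783% and 0.199% for MeHg at day 6, 18, 35 and 90, 7.48% for the mean MeHg difference, 0% for MeHg by age, 31.85% for the second control step, 0.8475% and 3.32% for the last step in controls and MeHg birds, 2.6% for MeHg by cohort, 16% for cohort and 9.53% for sex by age. The first step in both treatments, the second step in MeHg birds, sex over all ages and MeHg by sex stayed within 1.5 times their count in every alternative run. Where counts moved by more, the cause was not tested, apart from the random removals for sex by age. Fits with fewer libraries gave lower counts in some cases and higher counts in others.

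At day 6, 18, 35 and 90, edgeR with TMM called 0.192%, 0.248%, 0.206% and 0.532%, edgeR with DESeq2 size factors 0.192%, 0.248%, 0.22% and 0.532%, DESeq2 0.342%, 0.591%, 0.427% and 1.2% and voom with quality weights 0.285%, 1.94%, 1.83% and 3.52%. Both edgeR fits also changed the filter. MeHg by age was 0.0355%, 0.0355%, 0.0356% and 0.00712% in these tests. Voom also called 13.6% for the mean, 4.2% and 15.8% for the last step in controls and MeHg birds (1328 genes up and 890 down in the latter) and 3.98% for MeHg by cohort, and DESeq2 1.77% for the last control step. A pseudocount of 5 gave 0.0712% at day 6 and 0.313% at day 90, no filter 0.0578% at day 6 and 0.116% at day 35, and no covariates 0.0641% and 0.0427% at day 18 and 35, 10.6% for cohort and 2.66% for sex by age. Extraction batch gave 0.04985% at day 35 and 1.49% for MeHg by cohort. Surrogate variables gave 3.9% and 5.875% for the last step in controls and MeHg birds and 1.325% for MeHg by cohort. The title code within cohort (consensus correlation 0.10) gave 0.0214% at day 6, 3.06% for the mean, 1.47% for the last control step, 0.79% for MeHg by cohort and 7.66% for cohort. Over both cohorts (0.069) it gave 0.0214%, 0.04985% and 0.128% at day 6, 35 and 90 and 2.91% for the mean.

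With fewer libraries, those with a RIN gave 0.548% and 0.0285% at day 18 and 90, 3.92% for the mean, 19.9% for the second control step, 0.4415% and 2.03% for the last step in controls and MeHg birds, 1.17% for MeHg by cohort and 7.15% for cohort. With RIN added on them the values were 0.0214%, 0.541% and 0.0285% at day 6, 18 and 90, 4.06% for the mean, 20.1% and 0.385% for the second and last control steps, 1.26% for MeHg by cohort, 7.31% for cohort and 5.21% for sex by age. Males alone gave 0% at each age and 1.76% for the mean, and females alone 0%, 0.0142%, 0% and 0% and 0.491%. Cohort 1 alone gave 0.37%, 0.0285% and 0% at day 18, 35 and 90, 4.22% for the mean and 0% for sex by age. Cohort 2 alone gave 0%, 0.0142%, 0.04985% and 0.0783% at the 4 ages, 2.83% for the mean and 18.2% for sex by age. Sex by age was 0.0712% in controls alone and 0% in MeHg birds alone. Only the libraries of an age gave 0.00712%, 0.214%, 0.04985% and 0.0285%. Without plate H day 6 had 0.0783%. Without the 3 farthest libraries there were 0.2065%, 0.135% and 0.128% at day 18, 35 and 90, 6.32% for the last step in MeHg birds and 0.8475% for sex by age.

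Leaving out plates, codes or day 90 libraries in turn gave 0.0142% (without plate K) to 0.0855% (code C17) at day 6, 0% (plate G) to 0.748% (code C10) at day 18, 0% (plate J) to 0.15% (code Hg18) at day 35 and 0.00712% (plate J) to 5.79% (code Hg6) at day 90. The mean MeHg difference ranged from 3.94% (plate G) to 8.74% (code C19), MeHg by cohort from 1.2% (plate J) to 2.8% (code Hg18) and cohort from 9.785% (plate B) to 17.6% (plate G). The last step ranged from 0.42% (plate B) to 0.947% (plate C) in controls and 1.23% (plate J) to 3.45% (plate E) in MeHg birds. Sex by age ranged from 4.21% (without MeHg day 90 replicate 7) to 12%.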

Other observations

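The test of position along the developmental change was chosen after the result was seen, and the test of spread was chosen before.

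In the libraries analysed, 10144 of 14042 genes changed in at least 1 control step and 3898 in none. From day 6 to day 18, 2941 genes rose and 2663 fell that were called in neither later step, and 2200 turned direction in the second step. Whether early changes lasted to day 90 was not tested against day 6.

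A hypothesis was that MeHg birds of day 35 and day 90 may lie further along the day 6 to day 18 change than controls. The correlation across genes between their MeHg difference and that change was 0.092, and 24 of 100 splits with whole title codes gave a value as high (highest other 0.234), so the hypothesis found no backing. Another was that MeHg may alter the spread between birds of a group. The median log2 ratio of residual variance, MeHg over control, was -0.12, and 39 of 100 such splits lay as far from 0 (farthest other 0.403), so a changed spread was not detected.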
